A study of Homo sapiens with 6 samples.

How the data were processed

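The data are RNA sequencing libraries of Raji cells with a control shRNA (SHC002, 3 libraries) or a shRNA against OBF1 (3 libraries). Per the labels' protocols, cells were exposed to lentivirus for 5 days and selected for 7 days with 3 μg/ml puromycin. Libraries were made with a stranded poly(A) kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to a sample by its name.

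The authors deposited 1 table of raw, unnormalised read counts per gene, with 1 column per library and a column of gene lengths. The submitters' processing notes list the genome builds hg19 and mm9, and the organism is human. The aligner, counting tool, annotation, strand setting and filters are not given in the sources used here. How reads that map to near-identical genes were counted is likewise not given, so values of paralogs and overlapping genes are uncertain. The table has 23459 rows, named by numeric gene identifiers. Of these, 23308 matched an identifier in a RefSeq gene table of assembly GRCh38.p14. That table gave the symbols, the protein-coding label used for gene families, and the order used to find neighbouring genes. The 151 rows without a symbol held between 0.115% and 0.138% of the counts and stayed in the tests. Because that assembly differs from the listed builds, no coordinates are given. All 6 count columns were used, and 0 columns of per-sample values were left out.

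Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (min.count 10, min.total.count 15), which left 12010 genes, and libraries were scaled by the trimmed mean of M values (TMM). Groups were compared by the quasi-likelihood F test (glmQLFit, glmQLFTest) on all 6 libraries with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values were computed with the TMM-scaled library sizes. Total counts ranged from 29569281 to 32612429 per library, and the common biological coefficient of variation was 0.0269. On counts simulated for this comparison from the control means and the real library sizes, at that variation and with 11952 genes in the test, the fit recovered 79.2% of genes changed 1.25-fold, 90% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. In the simulation 6.19% of the called genes were unchanged. Only 48 to 50 tested genes were changed at each fold, whereas 75.4% of tested genes were called in the data. TMM scaling was thus not tested with so many changes, and these rates may not carry over.

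Before the data were examined, 18 gene lists were fixed: 3 primary lists (germinal centre programme, plasma cell programme, B cell identity and receptor signalling) and 15 secondary lists of pathways, signs of handling and markers of other cells. Older symbols were matched through the synonyms of the same table. The 16 lists with at least 2 tested members were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over those lists. Each test was repeated with the correlation estimated from the data and with fry. On simulated data camera called 2 of 2 planted lists and 0 of 14 unchanged lists. Genes were simulated independently of each other, so this does not show how often camera calls unchanged lists of correlated genes.

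The genes named in the text were chosen by a rule also fixed before the data were examined. It takes POU2AF1, POU2F1 and POU2F2, and the 8 largest changes in each direction among called genes with a mean of at least 5 CPM, a symbol and no overlap between the groups. It adds the members with the smallest p-values, up to 4 from each primary and up to 2 from each secondary list. It names 56 genes; any other gene was picked after its values were seen. The groups did not overlap for 76.6% of tested genes, where chance gives 10% for 3 libraries against 3.

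Alternatives were the Wald test of DESeq2 1.42.0, limma-voom, RLE size factors, upper-quartile factors, library sizes alone, no low-count filter beyond 1 count in total, a filter of 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library. Testing the fold change against 1.5 with glmTreat was added after the data were seen. Replicates were compared before averaging: chi-square per degree of freedom between pairs of libraries of 1 group ranged from 1.88 to 3.26, so no pair looked like 1 library deposited again. This test covers counting error only and does not show that the libraries came from separate cultures.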

Results

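Raji cells, an established Epstein-Barr virus-positive Burkitt's lymphoma line of germinal centre origin, carried a lentiviral short hairpin RNA (shRNA) against OBF1 or a non-targeting control hairpin, SHC002. OBF1, encoded by POU2AF1, is a B cell coactivator that binds DNA together with the Oct factors Oct1 (POU2F1) and Oct2 (POU2F2). Poly(A) RNA was sequenced from 3 libraries per group, numbered 1 to 3 in the labels. Total gene counts ranged from 29569281 to 32612429 per library, and between 14574 and 15062 genes had at least 1 count. Replicate libraries lay close together, with Spearman correlations of 0.999 within groups and between 0.968 and 0.972 across groups. The labels do not say whether the 3 libraries of a group came from separate cultures. The p-values below therefore measure the spread between these libraries, which may be technical.

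The targeted transcript was examined first, since the single comparison asks how the Raji transcriptome differs when OBF1 is lowered. POU2AF1 fell from 514 ± 2.15 normalised CPM (SD, n = 3) in control libraries to 242 ± 1.66 CPM (SD, n = 3) in OBF1 shRNA libraries. This was a 2.12-fold reduction (log2 fold change -1.09, SE 0.02, edgeR quasi-likelihood adjusted p = 1.25e-17), and the groups did not overlap. The control libraries held 512, 516 and 512 CPM and the OBF1 shRNA libraries 244, 241 and 241 CPM of the transcript. POU2F2, encoding Oct2, rose 2.50-fold, from 121 ± 1.73 to 303 ± 5.79 CPM (SD, n = 3, edgeR adjusted p = 4.81e-18). POU2F1, encoding the ubiquitous Oct1, was 1.19-fold lower, at 63.0 ± 3.07 CPM against 52.8 ± 0.522 CPM (SD, n = 3, edgeR adjusted p = 1.54e-05).

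**Figure D1:**
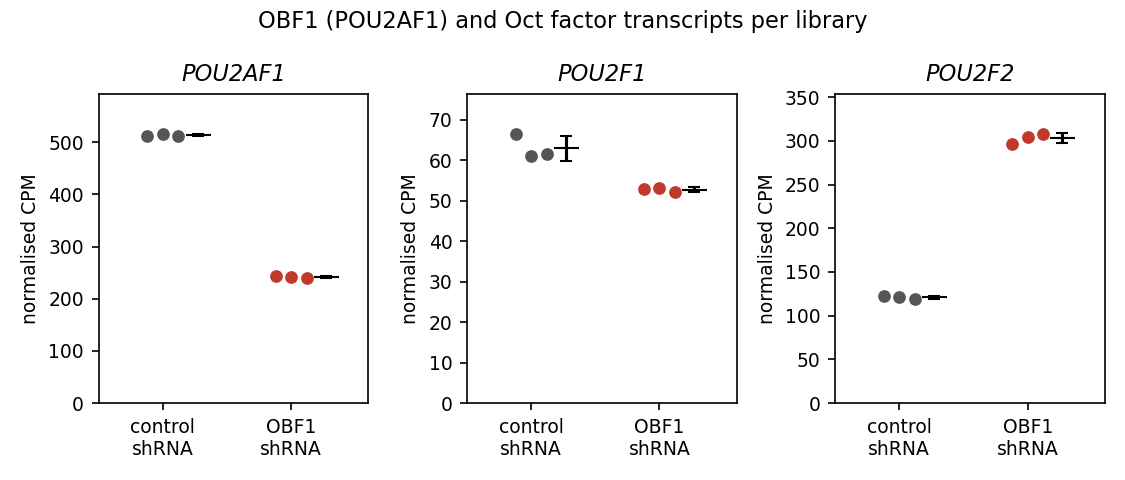
Normalised CPM (vertical axes, from 0) of POU2AF1, POU2F1 and POU2F2 in the 3 control shRNA and 3 OBF1 shRNA libraries; points are libraries, the bar beside them is the mean with its SD. POU2AF1 is 2.12-fold lower and POU2F2 2.50-fold higher in the OBF1 shRNA libraries, with no overlap between the groups.

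Most of the expressed transcriptome differed between the groups, and more genes were higher than lower among those that changed at least 4-fold. Of 12010 genes tested, 4508 were higher and 4550 lower in OBF1 shRNA cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), together 75.4% of those tested. Changes of at least 1.5-fold were called for 1550 higher and 1247 lower genes, and changes of at least 4-fold for 280 higher and 125 lower genes. The balance of directions depended on scaling. With library sizes alone, without a composition factor, all log2 fold changes moved by -0.11, and the calls became 3476 higher and 5778 lower, or 1297 higher and 1693 lower at 1.5-fold. When the fold change itself was tested against 1.5, an alternative added after the data were seen, 1180 genes were higher and 787 lower.

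FCRL5, an Fc receptor-like protein of the B cell surface, showed the largest gain among genes with a mean of at least 5 CPM over all libraries, from 0.226 ± 0.0891 to 22.9 ± 0.529 CPM (SD, n = 3). SLAMF1, a self-binding lymphocyte receptor, rose 59.6-fold to 113 ± 1.34 CPM (SD, n = 3). CCL22, the chemokine ligand of CCR4, rose 51.5-fold to 444 ± 1.70 CPM (SD, n = 3). The protease gene BACE2 rose 42.8-fold and the membrane semaphorin gene SEMA7A 35.0-fold. TNFRSF9, the costimulatory receptor 4-1BB, rose 27.7-fold. PTPN6, the SHP-1 phosphatase that restrains B cell receptor signalling, rose 24.7-fold from 3.37 ± 0.369 to 83.4 ± 1.02 CPM (SD, n = 3). BCL2A1, an anti-apoptotic BCL2 relative, rose 21.1-fold. Adjusted p-values for these 8 genes from the edgeR test ranged from 2.19e-24 for CCL22 to 3.22e-16 for BACE2.

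Among the 8 genes that fell furthest of those with a mean of at least 5 CPM over all libraries, GPD2, the mitochondrial glycerol-3-phosphate dehydrogenase, was 22.6-fold lower, falling from 9.60 ± 0.485 to 0.418 ± 0.158 CPM (SD, n = 3). PLOD2, a collagen lysyl hydroxylase, was 17.0-fold lower. The transcription factor gene SOX5 was also 17.0-fold lower, at 37.2 ± 1.24 CPM in control and 2.19 ± 0.239 CPM in OBF1 shRNA libraries (SD, n = 3). DEPTOR, an inhibitor of mTOR kinase, was 13.7-fold lower, and RIMS2, known from synaptic vesicle release, 9.95-fold lower. MAT1A, a methionine adenosyltransferase, was 7.76-fold lower and the actin regulator gene WASF3 fell from 16.4 ± 0.560 to 2.57 ± 0.471 CPM (SD, n = 3). CHAC1, a glutathione-degrading enzyme induced by ATF4, was 6.17-fold lower. Their edgeR adjusted p-values ranged from 3.24e-14 for WASF3 to 1.98e-18 for SOX5.

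**Figure D2:**
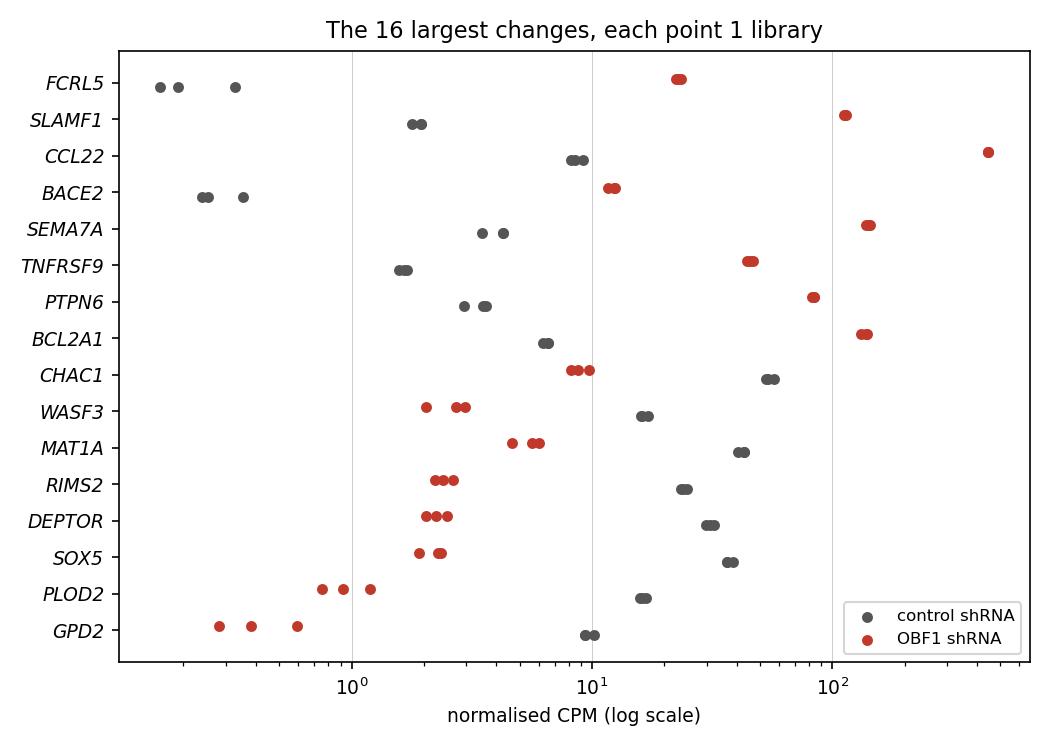
Normalised CPM (horizontal log axis) of the genes with the largest changes among those with a mean of at least 5 CPM, 8 in each direction, each point 1 library (grey control shRNA, red OBF1 shRNA). The groups do not overlap for any of these genes, as the selection required, and FCRL5 spans from 0.226 CPM (control mean) to 22.9 CPM (OBF1 shRNA mean).

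Genes of the germinal centre programme, which the series title names, split evenly between gains and losses. Of 29 tested members, 14 rose, 13 fell and 2 did not pass the edgeR test. Adjusted over the list alone, 15 rose and 13 fell. The gains included IRAG2, listed under its older name LRMP, at 2.33-fold, the interleukin-21 receptor gene IL21R at 3.00-fold and the G protein regulator RGS13 at 2.78-fold. MME, encoding CD10, was 2.11-fold lower, at 320 ± 4.51 against 152 ± 2.02 CPM (SD, n = 3). Further members, picked after their values were seen, fell too. BCL6, the master repressor of the programme, fell by 0.90 on the log2 scale (SE 0.03), from 261 to 140 CPM, and its partner activator MEF2B fell by 0.82. BACH2 fell by 1.54, CD38 by 1.56 and FOXO1 by 0.64. MEF2C rose by 0.93 on the same scale and SPIB by 1.19. As a set, the list did not differ from the other genes (camera, adjusted p = 0.565, and adjusted p = 0.599 with an estimated correlation). The rotation test fry, which asks whether members move on balance in one direction without comparing them with other genes, called the list higher (adjusted p = 8.96e-06), with a median log2 fold change of 0.07. Over all alternatives its adjusted p ranged from 8.96e-06 to 0.869.

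Plasma cell genes were lower more often than higher, with exceptions among the regulators. Of 22 tested members, 13 fell and 7 rose, over all genes and also adjusted over the list alone. Some of these calls, of genes named after their values were seen, were weak. TNFRSF17, lower, lost its call with DESeq2 (adjusted p = 0.108). It also lost it in edgeR without control shRNA replicate 2 (adjusted p = 0.0566), control shRNA replicate 3 (0.118) or OBF1 shRNA replicate 2 (0.208). With library sizes alone, FKBP11 and HSP90B1 lost their calls as higher and PDIA4 was called lower. XBP1, the transcription factor of the secretory programme, was 2.27-fold lower, at 240 ± 1.23 against 106 ± 1.74 CPM (SD, n = 3). ERN1, the kinase that activates XBP1 by splicing, was 4.05-fold lower. CD27 was 1.70-fold lower and SEL1L, of endoplasmic reticulum degradation, 1.63-fold lower. Among members picked after their values were seen, PRDM1, the regulator of plasma cell fate, fell from 6.81 to 0.733 CPM, while IRF4 rose from 0.619 to 7.91 CPM. The list as a whole was lower than other genes by camera (adjusted p = 0.0143). That call was lost with an estimated correlation (adjusted p = 0.26) and with limma-voom (adjusted p = 0.0975). With 1 library left out, the camera adjusted p ranged from 0.0112 to 0.0226. Over all alternatives the lowest adjusted p, 6.23e-05, came from fry, which does not compare the list with other genes, and the highest was 0.26.

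Genes of B cell identity and B cell receptor signalling were mostly higher. Of 32 tested members, 25 rose, 4 fell and 3 did not pass, over all genes and likewise adjusted over the list alone. MS4A1, encoding CD20, rose 2.96-fold, from 702 to 2078 CPM (log2 fold change 1.56, SE 0.02). CR2, the complement receptor CD21, rose 2.90-fold and FCER2, the low-affinity IgE receptor CD23, rose 10.6-fold. PTPN6, given above, belongs to this list as an inhibitor of the receptor. The 4 members that fell, named after their values were seen, were BANK1, CD79B, CD37 and TCF3. BANK1 fell by 1.36 on the log2 scale, from 4.83 to 1.86 CPM, and the last 3 by 0.12, 0.12 and 0.11. TCF3 lost its call without control shRNA replicate 2 (edgeR adjusted p = 0.0871), without OBF1 shRNA replicate 1 (0.0691) and without OBF1 shRNA replicate 2 (0.0608). Camera called the list higher (adjusted p = 1.16e-19, and adjusted p = 0.0103 with an estimated correlation). Of 16 immunoglobulin genes listed, 2 had rows and 1 was tested, so no set test was made. That gene, IGLL5, was 1.10-fold higher (edgeR adjusted p = 0.000947), and this call was lost with library sizes alone.

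Antigen presentation genes of MHC class II rose together. All 14 tested members were higher, each by at least 1.5-fold, with a median log2 fold change of 1.87 (camera adjusted p = 4.3e-55, and adjusted p = 0.00256 with an estimated correlation). HLA-DPB1 rose 4.18-fold, from 170 ± 4.16 to 712 ± 13.0 CPM, and HLA-DQA1 5.36-fold, from 61.6 ± 2.95 to 330.3 ± 8.50 CPM (SD, n = 3). CIITA, the transactivator of the family, rose by 1.73 on the log2 scale and CD74, the invariant chain, by 1.35; both were picked after their values were seen. Class II genes are similar in sequence and highly polymorphic, so values of single HLA genes are uncertain.

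Genes that NF-κB and CD40 signalling induce formed the list with the smallest camera p-value at the preset correlation. Of 26 tested members, 25 rose and 1 fell, RELA, named after its value was seen. The median log2 fold change was 1.75 (camera adjusted p = 5.78e-79, and adjusted p = 0.00158 with an estimated correlation). CCL22 led by p-value, followed by the signalling adaptor TRAF1, which rose 17.9-fold from 23.8 ± 0.999 to 428 ± 8.62 CPM (SD, n = 3). Interferon-stimulated genes were higher in 18 of 24 tested members and lower in 2 (camera adjusted p = 0.000491, and adjusted p = 0.0385 with an estimated correlation). IFIT3 rose 5.98-fold and OAS2 2.25-fold, while ISG20 and IFI44, named after their values were seen, fell. IFI44 lost its call with DESeq2 (adjusted p = 0.0651) and in edgeR without OBF1 shRNA replicate 1 (adjusted p = 0.0611). Beside these gains, the 15 markers of myeloid cells summed to 3.94 CPM in control and 4.07 CPM in OBF1 shRNA libraries. Of 5 tested, ITGAM was 1.96-fold higher and LYZ 3.81-fold lower, at 0.605 and 0.157 CPM (camera adjusted p = 0.846). The T and NK cell markers summed to 27.9 and 51.9 CPM, nearly all from IL7R, which rose 2.51-fold, and LCK. NKG7, the other tested member, was at 0.144 and 0.789 CPM. Over these 3 members the camera adjusted p was 0.171, while fry called them higher (adjusted p = 2.08e-05). None of 15 markers of 293T cells, in which the virus was packaged, passed the count filter, and they summed to 0.535 and 0.343 CPM. Without that filter 2 of these were called higher and 2 lower, and 3 myeloid markers were called higher.

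Migration and adhesion genes rose in 14 of 21 tested members and fell in 3 (camera adjusted p = 5.31e-08, and adjusted p = 0.0113 with an estimated correlation). CCR7, the receptor for lymph node homing, rose 11.0-fold from 28.7 ± 1.68 to 316 ± 4.09 CPM (SD, n = 3). GPR183, an oxysterol receptor that positions B cells outside the germinal centre, rose 13.0-fold to 172 ± 4.21 CPM (SD, n = 3). CXCR4, which guides cells to the dark zone and was picked after its values were seen, fell by 1.65 on the log2 scale, from 399 to 127 CPM, and ITGB1 and RASGRP2, also named after their values were seen, were the other members that fell. With library sizes alone, 5 members were lower, CCR6 and ITGA4 in addition, both named after their values were seen. In the apoptosis list, 9 of 25 tested members rose and 12 fell. Camera did not call it (adjusted p = 0.262), while fry called it higher (adjusted p = 1.69e-06). BCL2 rose 6.58-fold, from 10.6 to 69.7 CPM (log2 fold change 2.72, SE 0.05), and BCL2L1, encoding BCL-XL, rose 3.09-fold.

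Amino acid metabolism and sterol synthesis moved in opposite directions. All 17 tested members of the ATF4 and amino acid stress list fell, 16 of them by at least 1.5-fold. Without the low-count filter, 1 listed member was called higher. The median log2 fold change was -1.18 (camera adjusted p = 7.17e-34, and adjusted p = 0.0175 with an estimated correlation). ASNS, asparagine synthetase, was 3.94-fold lower, at 450 ± 3.58 against 114 ± 2.22 CPM (SD, n = 3), and SLC3A2, a subunit of amino acid transporters, was 3.50-fold lower. All 20 tested cholesterol synthesis genes rose, with a median log2 fold change of 1.32 (camera adjusted p = 9.9e-45, and adjusted p = 0.00158 with an estimated correlation). SREBF2, named after its values were seen, lost its call with library sizes alone (log2 fold change 0.03, edgeR adjusted p = 0.308). HMGCS1, which makes the precursor of mevalonate, rose 5.32-fold from 207 ± 2.44 to 1100 ± 9.87 CPM (SD, n = 3), and the sterol sensor gene INSIG1 rose 3.87-fold. Beside these changes, the heat shock and immediate early genes listed as signs of handling gave 9 higher and 5 lower of 18 tested. HSPA1B, a near copy of HSPA1A, was 3.58-fold lower and the co-chaperone gene DNAJB1 2.08-fold lower. Among members named after their values were seen, HSPH1, HSP90AA1 and FOSB also fell, while the immediate early genes EGR2 (10.3-fold), EGR1 (2.92-fold), JUNB (2.60-fold), ZFP36 (2.50-fold) and KLF6 (2.01-fold) rose. Camera did not call the list (adjusted p = 0.481), while fry called it lower (adjusted p = 0.0252). Its median of 0.16 and mean of 0.22 were above 0 while camera and fry pointed down.

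Mitotic genes were mostly lower, by small amounts. Of 28 tested G2/M genes, 27 fell and 1 rose, BUB1, named after its value was seen, with a median log2 fold change of -0.35. PTTG1, named after its values were seen, was among the 27 (edgeR adjusted p = 0.0456), and lost its call with DESeq2 (adjusted p = 0.117), RLE size factors, no low-count filter and the replicate block (adjusted p = 0.0614). It also lost it with any library but OBF1 shRNA replicate 3 left out, and KIF20B, likewise named afterwards, lost its call without control shRNA replicate 3 (edgeR adjusted p = 0.0767) or OBF1 shRNA replicate 1 (edgeR adjusted p = 0.0712). HMMR, a spindle protein gene, was 1.63-fold lower, at 232 ± 2.12 against 142 ± 2.76 CPM (SD, n = 3), and the checkpoint kinase gene TTK 1.58-fold lower. Camera called the list lower (adjusted p = 3.72e-06), and the call was lost with an estimated correlation (adjusted p = 0.186). Genes of G1/S and replication divided into 12 higher and 9 lower of 28 (camera adjusted p = 0.846), while fry called the list higher (adjusted p = 0.0077). CCND3, a D-type cyclin, was 1.64-fold higher and the primase gene PRIM1 1.39-fold lower. MYC targets divided into 12 higher and 10 lower of 30 (camera adjusted p = 0.846). PPAN, of ribosome assembly, was 1.37-fold higher and the mitotic kinase gene PLK1 1.44-fold lower. Median and mean of the MYC targets, 0.01 and 0.03, were above 0 while camera pointed down. With library sizes alone, the counts became 7 higher and 17 lower for the MYC targets, and 16 members of the G1/S list were lower.

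**Figure D3:**
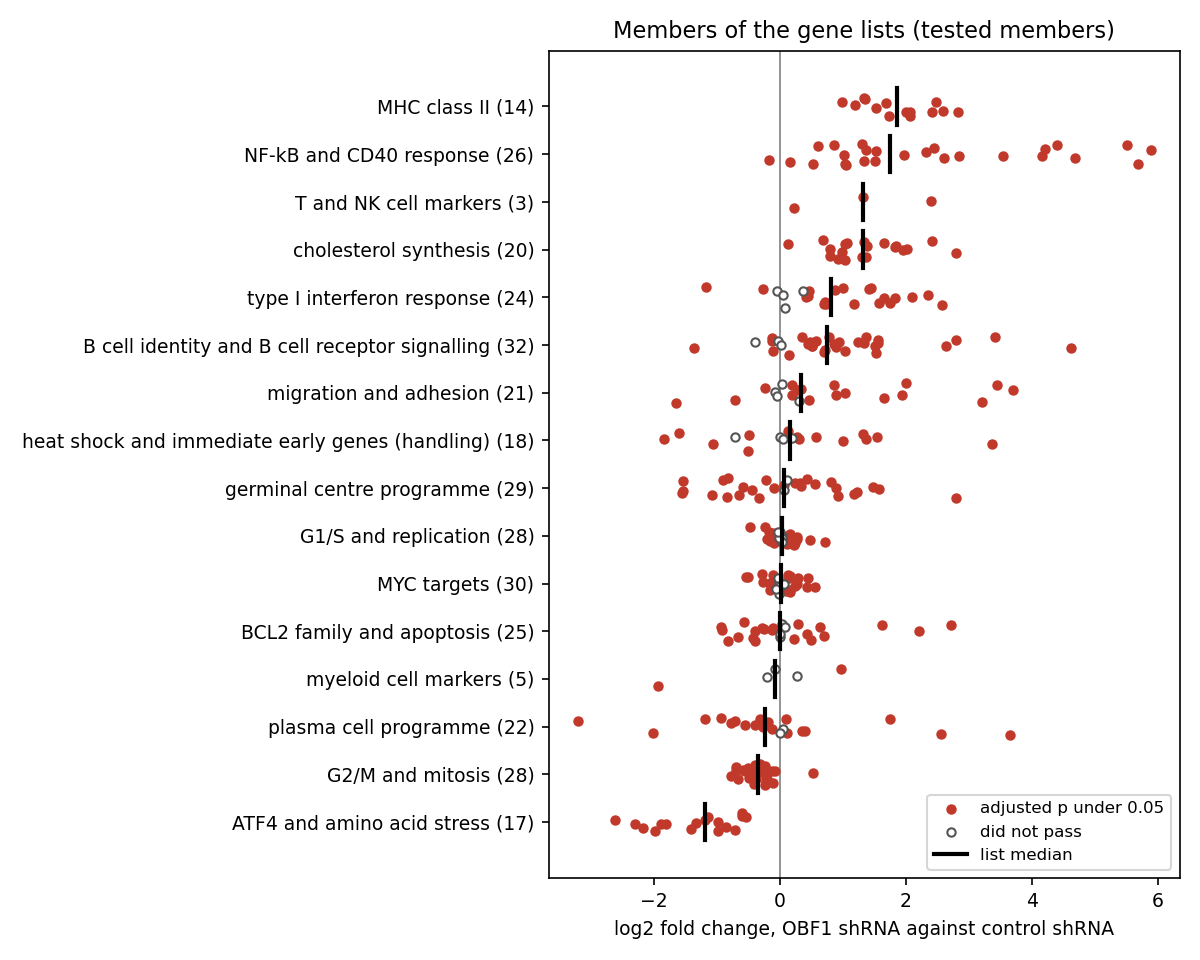
Log2 fold change of OBF1 shRNA against control shRNA (horizontal axis) for every tested member of the 16 gene lists with at least 2 tested members, whose number is in brackets; filled points passed the edgeR test at an adjusted p of 0.05, open points did not, and black bars are list medians. Medians run from -1.18 for the ATF4 and amino acid stress list to 1.87 for MHC class II.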

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

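One alternative, the glmTreat test of the fold change against 1.5, was chosen after seeing the data. The number of called genes, 9058, ranged from 8344 with DESeq2 to 9547 without a low-count filter over the alternatives, and leaving out 1 library gave 8632 to 8974. Between 8474 and 8671 of the calls remained with a library left out, in the same direction, and 0 reversed. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.01, -0.12 and -0.06, and with the replicate block 8759 genes were called; no library correlated best with its own number, and the block changed no call of a list or of the genes named by rule. Of 781 values of the 56 named genes under alternatives, 780 kept direction and call. The exception was IGLL5 with library sizes alone (log2 fold change 0.03). Most of these genes were chosen for large changes or small p-values in the same libraries, so their calls were likely to hold. The share does not carry over to other genes: list members such as PTTG1 and TCF3 lost their calls in several settings. The glmTreat test called 787 lower genes against 1247. The plasma cell list lost its camera call with limma-voom (adjusted p = 0.0975) and with an estimated correlation (adjusted p = 0.26), where the mitotic list lost its call too. The cause of these losses was not tested. Camera called 7 of the secondary lists, and 6 with an estimated correlation. Fry, which does not compare a list with other genes, called 11 of them and also the germinal centre list (fry adjusted p = 8.96e-06). The secondary lists called by fry but not by camera were apoptosis, T and NK cell markers, G1/S and handling. Lists without a camera call changed direction in some settings. MYC targets did so with limma-voom (camera adjusted p = 0.873), without a filter (camera, 0.905) and with fry (fry adjusted p = 0.309). Over libraries left out their camera adjusted p was 0.825 to 0.958, upward without control shRNA replicate 2 only. The handling list did so with limma-voom (camera, 0.869), and G1/S genes (camera, 0.813) and myeloid markers (camera, 0.933) with library sizes alone. The cause was not tested. Lists were not tested with DESeq2. With simulated counts at these library sizes 79.2% of the smallest simulated changes were recovered; genes under the count filter were not assessed.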

Other observations

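The gene families and additional lists below were drawn up after the main comparison was seen, the families from the symbols of protein-coding genes, and the single genes named from them were picked after their values were seen. Of the tests weighed here, those of the length trend, the spread between replicates and the myeloid total were chosen only after the result was seen. Genes of the translation and respiration machinery were among the many small changes. Of 79 tested cytosolic ribosomal protein genes, 74 were higher in OBF1 shRNA cells and RPL39L, RPL7L1 and RPS26 lower, with a median log2 fold change of 0.38 (72 higher and 4 lower with library sizes alone). With the trend of fold change with gene length removed, this median became 0.22. NADH dehydrogenase subunits were higher in 29 of 34, with NDUFB9 and NDUFS4 lower (26 higher and 5 lower with library sizes alone). Mitochondrial ribosomal proteins were higher in 49 of 77 and lower in 13 (camera adjusted p = 0.199), where library sizes alone gave 31 higher and 23 lower. Cytosolic aminoacyl-tRNA synthetases were lower in 12 of 17, among them CARS1 (130 against 59.5 CPM) and GARS1 (962 against 534 CPM). Zinc finger genes of the ZNF series were lower in 226 of 373 and higher in 55, with a median of -0.26 (255 lower and 30 higher with library sizes alone). Camera called the ribosomal (adjusted p = 2.31e-10), NADH dehydrogenase (0.0035), synthetase (0.000687) and ZNF families (0.000687) over 12 families, and with an estimated correlation these became adjusted p = 0.48, 0.524, 0.287 and 0.287. It also called the interleukin receptors (11 higher and 5 lower of 18, adjusted p = 0.0028, and 0.148 with an estimated correlation) and the TNF receptor and ligand superfamily (8 higher and 5 lower of 16, adjusted p = 0.0193, and 0.287 with an estimated correlation).

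Of 7 tested Fc receptor-like genes, 5 rose and 0 fell by edgeR, while library sizes alone gave 1 lower. Their median log2 fold change was 2.64 (camera adjusted p = 7.36e-08, and adjusted p = 0.148 with an estimated correlation). The family holds FCRL5, already seen as the largest gain, and FCRL1, FCRL2 and FCRL3 of the B cell identity list, so it is not separate evidence. Fatty acid synthesis genes rose in 8 of 10 tested, and FADS2 fell. SCD, the stearoyl-CoA desaturase, rose 2.12-fold to 1424 ± 8.63 CPM and FASN, fatty acid synthase, 1.73-fold to 617 ± 6.64 CPM (SD, n = 3). CHI3L2, a chitinase-like protein gene, rose 7.42-fold from 134 to 992 CPM.

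The number of called genes, 9058 of 12010, is large for a 2.12-fold reduction of 1 transcript. Library sizes alone gave 9254 calls, but this count cannot decide whether composition scaling caused the number. The shift of about -0.11 can itself make calls, and calls of lower genes rose from 4550 to 5778. Of the 9058 calls, 8026 kept their direction with library sizes alone, so these did not rest on the composition factor. Which of the smaller changes were called did depend on scaling. A gene length trend was present, with a Spearman correlation across genes of -0.17 between fold change and length, but removing it left 9111 calls, so it is not the whole cause. The common biological coefficient of variation was 0.0269; libraries drawn from 1 culture per hairpin might give so small a spread, and the labels do not settle whether cultures were separate, so differences between cultures and an effect of OBF1 cannot be told apart. Of the 10 splits of the 6 libraries, only 1, the real one, gave as many genes (9058, and 2797 at 1.5-fold), the highest other split gave 0 at either threshold, and 10 splits are too few for a share under 0.05.

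The rise of NF-κB, CD40 and MHC class II genes raises the question of whether the cells of the groups differ in more than OBF1. Myeloid cells that carry the 15 listed markers are argued against, because these markers reached at most 4.3 CPM in an OBF1 shRNA library with LYZ at 0.157 CPM, while CCL22 alone stood at 444 CPM. Dendritic cells stay open, since the list holds no marker particular to them. Different cell lines or donors stay open: 0 of 25 genotype-determined genes with a row were present in 1 group only. Of the 16 tested, 6 were higher and 5 lower, with a median log2 fold change of 0.04. Yet CHI3L2 was 7.42-fold, IRF5 3.10-fold and UTS2 2.03-fold higher. HLA-DRB4 was 3.99-fold higher, but it is itself an MHC class II gene, so it cannot tell a donor difference from the rise in question. A difference in chromosome copy number stays open too, since the largest deviation of a median over 100 neighbouring genes was 0.25 on the log2 scale, which 1 of 100 shuffled gene orders reached. As a hypothesis, stronger Epstein-Barr virus latency expression may accompany the OBF1 hairpin: 13 tested host genes associated with latency and outside the fixed lists had a median log2 fold change of 1.64 with 11 higher and 0 lower, among them VIM, FGR and BATF, but such genes also respond to NF-κB, viral transcripts were not analysed here, and an effect of OBF1 itself is untested with 1 hairpin.

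The fall of ATF4 and amino acid genes and the rise of cholesterol genes could reflect the state of the cultures. Composition scaling is argued against for these 2 lists. Library sizes alone moved log2 fold changes by about -0.11, against list medians of -1.18 and 1.32. Both lists thus kept at least 0.917 of their median, which follows from that shift and is no separate test. Denser, oxygen-poorer control cultures stay open, since 15 tested hypoxia genes had a median log2 fold change of -0.0618, with 5 higher and 7 lower: VEGFA was 1.99-fold, KDM3A 1.77-fold and MXI1 1.27-fold lower, while ALDOC was 7.17-fold and PFKFB4 2.03-fold higher, against this explanation. General endoplasmic reticulum stress in the control cultures is undecided. The 12 unfolded protein response genes had a median of 0.0430, and a bound set before this value was seen counts a median that is not negative against this explanation. Yet the genes went both ways, with 6 higher, 5 lower and quartiles of -0.30 and 0.31. Of response genes held in the plasma cell list, ERN1, XBP1, DNAJB9, SEL1L and HERPUD1 fell by 4.05-fold to 1.46-fold. HSP90B1 rose 1.08-fold and DERL3 1.32-fold, and HSP90B1 lost its call with library sizes alone (edgeR adjusted p = 0.868). An effect of OBF1, which the design names, was not separated from culture conditions.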
